A study of Mus musculus with 6 samples.

How the data were processed

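RNA was measured in Lin- Sca1+ cKit+ cells of mouse bone marrow, a sorted population rich in haematopoietic stem and progenitor cells. All mice were homozygous for FLT3-ITD, an internal tandem duplication that keeps the receptor tyrosine kinase FLT3 active. The microRNA miR-155 was wild type in the control group (FLT3-ITD) and deleted in the other group (FLT3-ITD miR-155 KO, below KO). Each group had 3 libraries, and each library held the pooled RNA of 3 mice, so the p-values measure the spread between pools. Groups and replicate numbers were taken from the labels.

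Gene counts had been made by the authors and were deposited as whole numbers per gene and library, with no normalization. The authors also deposited FPKM values, which were the counts times a factor per gene and a factor per library: over genes with a count above 100, the ratio of FPKM to count between libraries varied by 0.0%. Only the counts were tested. The deposited table further held the authors' own comparison, with a log2 fold change per gene and an adjusted p-value for 16577 genes. In that comparison 106 genes had an adjusted p under 0.05, 7 higher and 99 lower in the KO. Per the submitters' processing notes, Novoalign 2.08.01, DESeq2 1.10.1 and the mm10 build were used. The read counter, its annotation and its use of strand were not given in the sources used here. Counts of near-identical genes (immunoglobulin V segments, Hspa1a and Hspa1b, Gbp4 and Gbp6, H2-Q6 and H2-Q7, Erdr1) are therefore uncertain, since shared reads could have been split or dropped, and so are those of overlapping and antisense genes.

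The table held 22475 genes, of which 21966 matched an identifier of GENCODE M21 (GRCm38, the same assembly as mm10). Coordinates, biotypes and 3' UTRs were taken from that annotation. Symbols were missing for 311 genes, and 23 had been turned into dates, so genes were joined by identifier. Totals lay between 6843129 and 9443615 counts per library. Counts of 3, the limit that a count of 0 allows, corresponded to 0.318 to 0.438 CPM (counts scaled to a common library size), and intervals on counts cover counting error only.

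The groups were compared with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr (minimum count 10, minimum total 15) and the two-sided quasi-likelihood F test on the group alone. The 13217 genes left were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every log2 fold change is KO over control, and its standard error (SE) was derived from the F statistic. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 33 lists fixed before the data were examined. The 3 lists of immunoglobulin, plasma cell secretory and regulatory T cell genes were chosen after the values were seen and were adjusted together with those 33. For miR-155-5p, genes with an 8mer seed match in the longest annotated 3' UTR were compared with genes that had no site, and with 839 shuffled 8mers. Single ratios were compared with exact permutation tests in scipy, two-sided, whose smallest possible p is 0.1 for 3 against 3.

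Replicate numbers from the titles recur in both groups, and the labels do not say what they share. Deviations from the group means correlated across genes by r = 0.57, 0.53 and 0.22 between libraries with equal numbers 1, 2 and 3, and by 0.54, 0.50 and 0.20 without genes on X and Y. Every pair lay above 0.1, the limit set for treating the numbers as pairs. Control replicate 3 and KO replicate 2, with unequal numbers, also did (r = 0.13, and 0.11 without X and Y), and the other 5 unequal combinations did not. Deviations within a group cancel out, so these r are not independent of each other. By Spearman correlation of log2 CPM, KO replicate 3 was slightly closer to control replicate 2 (0.9871) than to control replicate 3 (0.9860). So the pairing rests on the data and not on a stated litter or day. The pools also matched by number in the RNA of Xist and Ddx3y, which mark female and male cells. The comparison without a block remained the one fixed beforehand, and the fit with the replicate number as a block is given beside results that it changed. The block left 2 residual degrees of freedom, against 4 without it.

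The genes named are the miR-155 host gene, Kit, Ly6a and Flt3. To these were added the up to 10 largest rises and falls past the threshold with groups that did not overlap and a mean log2 CPM of at least 1. The up to 4 members with the smallest p of each list that passed, and of the interferon-stimulated and miR-155 target lists, were also taken, as were Inpp5d, Socs1, Cebpb, Bach1, Spi1 and Jarid2. Other genes are said to have been chosen after their values were seen. A gene that this rule selects is not reported here.

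On counts simulated for this comparison (13046 genes tested, 50 genes changed at each fold), the fit without a block recovered 26% of 1.5-fold, 66% of 2-fold, 98% of 4-fold and 100% of 8-fold changes. With the block the shares were 18%, 60%, 96% and 100%. The changed genes were drawn only from genes with a mean count of at least 50. Recovery among genes with fewer counts was therefore not measured. Of 200 simulated lists without a shift, 6 reached p under 0.05 without the block and 4 with it. False calls made up 6.25% of the calls without the block and 8.50% with it. Genes were drawn independently of each other, without an effect shared by libraries of equal number. So these shares do not give the error rate of lists whose members move together, nor the gain of a block where pairs differ.

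Alternatives were other size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, the block, a threshold of 0.1 and leaving out each library. List tests were also run with an estimated correlation and with fry. Chosen after the data were seen were library sizes without immunoglobulin genes, the bias-adjusted quasi-likelihood test, the block combined with an estimated correlation or fry, and leaving out both libraries of a number.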

Results

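The data were 6 RNA-seq libraries of sorted stem and progenitor cells, 3 from FLT3-ITD mice and 3 from FLT3-ITD mice without miR-155. Library totals were 9443615, 8585695 and 8136914 counts in the control group and 6843129, 7601317 and 7157206 in the KO group. Immunoglobulin genes took 3.13% ± 0.65 (SD, n = 3) of the control counts and 0.938% ± 0.533 (SD, n = 3) of the KO counts. Spearman correlations of log2 CPM lay between 0.965 and 0.990 over all pairs of libraries. Replicates of a group differed by more than sampling noise, with a chi-square of at least 7.80 per degree of freedom.

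The miR-155 host transcript was lower in the KO libraries. Gm26667, the long noncoding RNA annotated at the Mir155 host locus (ENSMUSG00000097418, chromosome 16, 84703167 to 84715245, GRCm38), had 33, 48 and 36 counts in the control libraries and 4, 14 and 4 in the KO libraries. Its log2 fold change was -2.14 ± 0.46 (SE), with an adjusted p of 0.274 in edgeR, and -2.20 ± 0.35 (SE) with an adjusted p of 0.0377 with the replicate block. The hairpin Mir155 itself (chromosome 16, 84714140 to 84714204, inside that transcript) had 2, 1 and 0 counts in the control and 0 in each KO library, too few to compare. How much of the host transcript the deletion removed was not given in the sources used here. The gate and genotype genes Kit (-0.12), Ly6a (0.11) and Flt3 (-0.05, log2 fold change) did not pass the threshold, with an adjusted p of 0.9995 each in edgeR.

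The comparison asked which genes of FLT3-ITD progenitors differ when miR-155 is missing. Interferon-inducible genes were higher and immunoglobulin genes lower in the KO libraries. Cxcl10, a chemokine, rose from 13.7 ± 0.355 to 31.4 ± 3.51 CPM (SD, n = 3), and Iigp1, an interferon-inducible GTPase, from 49.99 ± 4.84 to 94.98 ± 6.55 CPM (SD, n = 3). Their log2 fold changes were 1.20 ± 0.13 and 0.93 ± 0.10 (SE), each with an adjusted p of 0.0339 in edgeR. Of the 13217 genes tested, 21 passed the threshold, with 2 higher and 19 lower. The 19 were 18 immunoglobulin genes and Slpi, a secreted protease inhibitor named after its value was seen, which fell by 1.55 ± 0.18 (SE; adjusted p 0.0369). With the replicate block 180 genes passed, 42 higher and 138 lower, among them all 21, and 95 of the lower genes were immunoglobulin genes. Without FLT3-ITD replicate 1 or FLT3-ITD replicate 3, 0 genes passed in edgeR (766 and 358 had an unadjusted p under 0.05). Without FLT3-ITD replicate 2 or KO replicate 2, 9 and 8 passed, none of them higher, and DESeq2 on all libraries called 131.

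**Figure D1:**
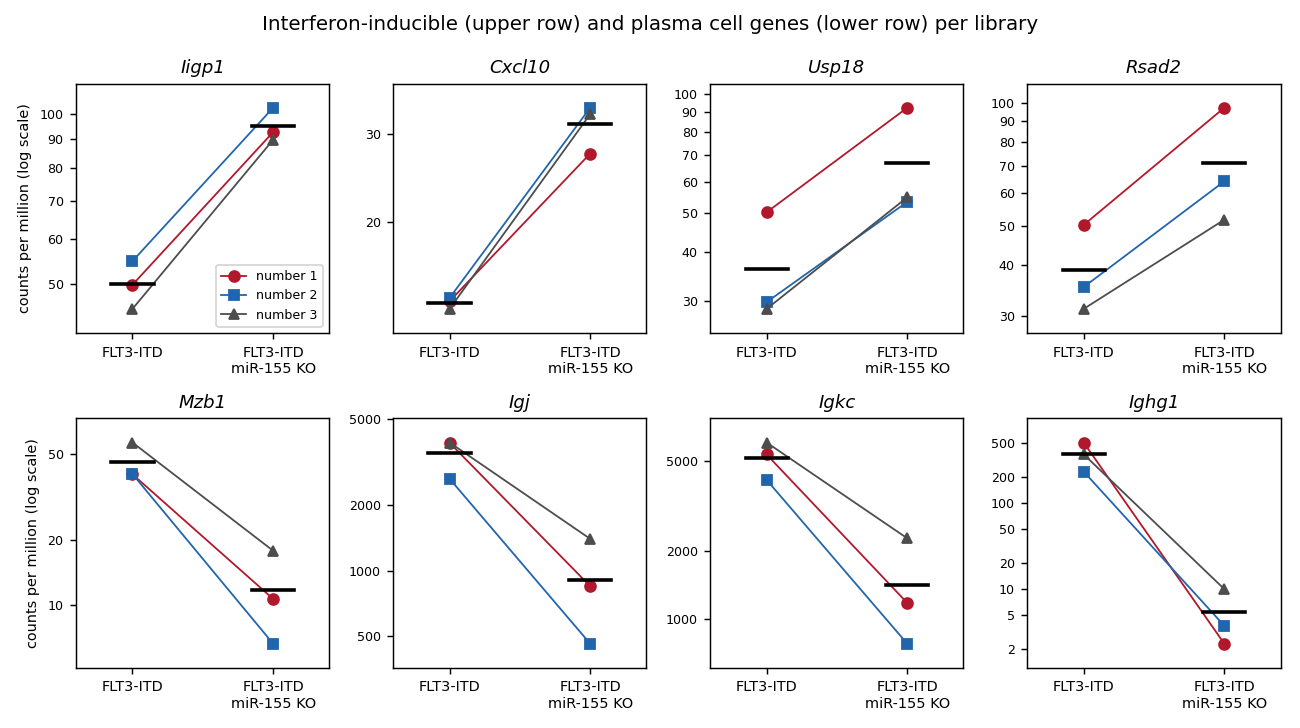
CPM on a log axis for 4 interferon-inducible genes (upper row) and 4 plasma cell genes (lower row) in each library, with lines joining libraries of equal replicate number and black bars at group means. Iigp1 lay higher and Ighg1 lower in every KO library than in every control library.

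Type I interferon-stimulated genes were higher in the KO as a group. Of 46 measured members, 45 had a positive fold change, 40 were higher in all 3 pairs of equal number, and the median log2 fold change was 0.49 (camera adjusted p = 4.3e-24; 0.23 without KO replicate 1, adjusted p 6.1e-14). With an estimated correlation the list did not pass (adjusted p = 0.497; with the block, 0.481). No member passed over all genes, nor adjusted over the list alone, whereas with the replicate block 15 rose over all genes and 41 adjusted over the list alone. With that block Usp18, a negative regulator of interferon signalling, rose by 0.88 ± 0.08 (SE; adjusted p 0.00314 in edgeR, 0.883 without the block). Rsad2, an antiviral protein, rose by 0.85 ± 0.08 (adjusted p 0.00477, 0.762 without the block), and Oas3 and Oasl1 by 0.70 and 0.81 (0.0115 and 0.0140). The pairs of numbers 1, 2 and 3 had list medians of 0.68, 0.40 and 0.30. Relative to each gene's mean over the libraries, the list medians were 0.01, -0.29 and -0.39 in control replicates 1, 2 and 3 and 0.71, 0.13 and -0.08 in the KO replicates, so the groups overlapped. Both libraries of number 1 also had higher macrophage gene levels (list medians 1.70 in the control and 1.33 in the KO, against -1.14 to -0.28 in the others), and KO replicate 1 had the highest medians of MHC class II (0.85) and dendritic cell genes (0.74).

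Interferon-gamma-inducible GTPases and chemokines (22 measured) had a median of 0.40 (camera adjusted p = 4.1e-17, and adjusted p = 0.107 with an estimated correlation). Cxcl10 and Iigp1 rose, 8 members rose adjusted over the list alone, and with the block 3 rose, or 13 adjusted over the list alone. Gbp6 (1.13, adjusted p 0.338) and Gbp4 (0.60, adjusted p 0.429), guanylate-binding proteins, did not pass in edgeR. MHC class I presentation (17 measured, all with a positive fold change) had a median of 0.20 (camera adjusted p = 3.7e-06) and the interferon receptor and signalling chain (17 measured) 0.14 (2.0e-04). Both had an adjusted p of 0.497 with an estimated correlation. The peptide transporter Tap1 (0.27), H2-Q6 (0.23), H2-Q7 (0.27), Psmb10 (0.20), Ifnar1 (0.24) and Irf9 (0.33) did not pass. Without KO replicate 1 the MHC class I median was 0.08 (adjusted p 0.00348) and the receptor and signalling chain lost its call (median 0.05, adjusted p 0.0605). The chain's median was 0.24 without KO replicate 2 and 0.23 without KO replicate 3.

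NF-kB response genes (20 measured, median 0.34, camera adjusted p = 4.4e-05) and immediate-early genes (18 measured, median 0.21, camera adjusted p = 0.00734) were also higher as lists. With an estimated correlation neither passed (adjusted p = 0.497 and 0.819). No member of either passed over all genes, with or without the block, and 1 NF-kB response gene, Ccl4, rose with the block adjusted over the list alone. Icam1 (0.40), Ccl4 (0.63), Tnfaip2 (0.27) and Nfkbie (0.38) had the smallest p of the first list, and Atf3 (0.48), Btg2 (0.41), Klf2 (0.41) and Dusp1 (0.30) of the second. The NF-kB median was 0.20 without FLT3-ITD replicate 1, 0.16 without FLT3-ITD replicate 3, 0.18 without KO replicate 1 and 0.19 without KO replicate 2, and the list kept its call in each. The immediate-early list lost its call without FLT3-ITD replicate 1 (median 0.09, adjusted p 0.220), FLT3-ITD replicate 3 (0.11, 0.242) or KO replicate 2 (0.07, 0.0805). Its median was 0.45 without FLT3-ITD replicate 2, 0.14 without KO replicate 1 and 0.35 without KO replicate 3.

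Plasma cell genes were lower in the KO. Among the largest falls, Ighg1, the constant region of an IgG heavy chain (chromosome 12, 113325240 to 113330523), fell from 367 ± 136 to 5.31 ± 4.06 CPM (SD, n = 3), a log2 fold change of -6.09 ± 0.51 (SE; adjusted p 0.0188 in edgeR). Ighg2c fell from 1316 ± 317 to 36.3 ± 27.4 CPM (SD, n = 3). The V segments Igkv2-109 (-3.47), Ighv14-3 (-3.48), Ighv1-64 (-3.44), Igkv6-17 (-3.76), Igkv14-111 (-4.30), Igkv17-121 (-4.33) and Igkv3-7 (-4.61) also fell. Ighv9-2 fell from 237 counts over the control libraries to 3 over the KO libraries, a ratio of 65.2 with a 95% counting interval of 22.05 to 319. Mature B and plasma cell genes, a list fixed beforehand (7 measured), had a median of -0.85 (camera adjusted p = 2.3e-05, and adjusted p = 0.469 with an estimated correlation), or -1.52 without KO replicate 1 and -0.40 without KO replicate 2. With the block Mzb1, a chaperone of immunoglobulin assembly (-2.02), Igj, the joining chain (-2.07), and Prdm1, the regulator of plasma cell identity (-1.54), fell, with adjusted p of 0.00317, 0.00432 and 0.0185. Adjusted over the list alone, 3 members fell without the block and 4 with it. The B cell gene Ms4a1 (-0.57) did not pass.

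Other cell type lists were lower by smaller margins. Mature neutrophil and monocyte genes (19 measured) had a median of -0.52 (camera adjusted p = 5.4e-05, and 0.497 with an estimated correlation). Their medians were -0.90, 0.02 and -0.22 in the pairs of numbers 1, 2 and 3, and 7 members had a positive fold change. Ngp (-0.73), Ltf (-0.70), Camp (-0.84) and Retnlg (-0.86), neutrophil granule or secreted proteins, did not pass over all genes, and 9 members fell adjusted over the list alone. With the block 1 member passed over all genes, Ms4a6c, which rose by 0.54 (adjusted p 0.0430) and was named after its value was seen. Without FLT3-ITD replicate 1 the list lost its call (adjusted p 0.191). T and NK cell genes (18 measured) had a median of -0.23 (camera adjusted p = 0.00642, and 0.469 with an estimated correlation), and with the block the costimulatory receptor Cd28 (-1.14) and the inhibitory receptor Ctla4 (-1.54) fell. Cd2 (-1.27) and Cd3g (-0.63) did not pass. That list lost its call without FLT3-ITD replicate 1 (median -0.03, adjusted p 0.138) or KO replicate 3 (-0.19, 0.110), and its median was -0.09 without KO replicate 2. Mast cell, basophil and eosinophil genes (9 measured, median -0.13) and lymphoid progenitor genes (13 measured, median -0.09) had camera adjusted p of 0.00783 and 0.0101, and 0.497 and 0.469 with an estimated correlation. With the block Prg2, an eosinophil granule protein, fell by 1.72 (adjusted p 0.00929, 0.0881 without the block), while Il1rl1 (-0.95), Prss34 (-0.57) and Gzmb (0.56) did not pass. The B cell receptor genes Cd79a (-1.63) and Cd79b (-0.52) and the adaptors Lax1 (-0.88) and Blnk (-0.85) did not pass. With the block 1 member of the lymphoid list did, the heavy chain gene Ighm, named after its value was seen (-0.87, adjusted p 0.0195). The mast cell list lost its call without KO replicate 1 (median -0.02, adjusted p 0.375), and its median was -0.30 and -0.24 without FLT3-ITD replicates 1 and 3 and -0.36 and -0.28 without KO replicates 2 and 3. The lymphoid list lost its call without FLT3-ITD replicate 1 (adjusted p 0.138) or KO replicate 2 (0.184), and its median was -0.05 without FLT3-ITD replicate 2, -0.25 without KO replicate 1 and -0.05 without KO replicate 3.

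In all, 11 of the 33 lists passed, 6 higher and 5 lower, and none did with an estimated correlation (smallest adjusted p = 0.107). The other 22 lists had camera adjusted p from 0.0735 to 0.941. With the block those 11 and 4 more passed: MHC class II presentation (blocked median 0.20, adjusted p 0.0414), haematopoietic stem cell markers (-0.20, 5.1e-04), erythroid genes (-0.31, 0.0108) and macrophage genes (0.06, 0.0400). With the block and an estimated correlation their adjusted p were 0.904, 0.481, 0.904 and 0.904. MHC class II genes had medians of 0.86, 0.12 and -0.37 in the pairs of numbers 1, 2 and 3, and 0 of 10 members were higher in all 3 pairs. Without the block the macrophage list had a median of -0.22 while its test pointed upward (adjusted p 0.414). No member of these 4 lists passed over all genes.

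**Figure D2:**
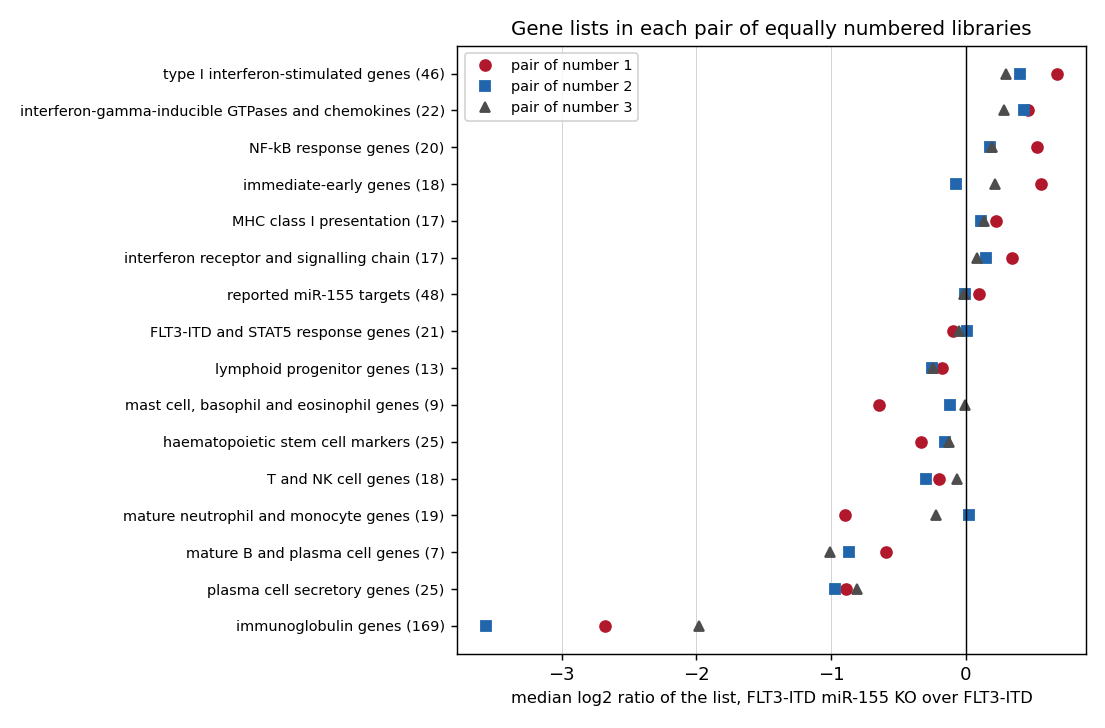
Median log2 ratio of KO over control for gene lists in each pair of libraries with equal replicate number, with the number of measured genes in brackets. Type I interferon-stimulated genes had medians of 0.68, 0.40 and 0.30, and plasma cell secretory genes, a list chosen after the values were seen, of -0.89, -0.97 and -0.80.

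Reported miR-155 targets did not shift as a group. The 48 measured members had a median log2 fold change of 0.04 (camera adjusted p = 0.528), and 0 rose and 0 fell over all genes. Adjusted over the list alone, 1 rose, Cebpb, and 2 fell, Trp53inp1 and Ctla4. With the block 0 rose and 3 fell: Trp53inp1, a stress-induced p53 partner (-0.85, adjusted p 0.0218 in edgeR), Ctla4 (-1.54, 0.0368) and the transcription factor Ets1 (-0.51, 0.0381). The phosphatase Inpp5d (0.15), Socs1 (0.25), Cebpb (0.53), Bach1 (0.03), Spi1 (0.24) and Jarid2 (0.19) did not pass over all genes. There the adjusted p of Cebpb was 0.347 in edgeR (0.105 with the block). Genes with an 8mer seed match of miR-155-5p (395 genes, sequence AGCATTAA in the 3' UTR) had a median 0.009 above that of 10088 genes without a site (limma camera, p of 0.528). The difference computed for the comparison with 839 shuffled 8mers, 0.00878, lay at percentile 93.7 among them. Of the 395, 0 rose and 0 fell, and with the block 2 fell, Trp53inp1 and Ets1.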

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

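Of 76 genes selected for naming, each under 14 alternatives (not the threshold of 0.1 nor leaving out both libraries of a number), 948 of 1064 values kept their direction and their side of the threshold, 54 newly passed, 55 no longer passed and 7 reversed. The 76 include genes chosen after their values were seen because they passed with the block. Part of the newly passing values was therefore fixed by that choice. The reversed values were of genes that passed nowhere: leaving out 1 library gave -0.286 to 0.0334 for Kit, -0.190 to 0.0355 for Flt3, -0.0387 to 0.0752 for Bach1 and -0.00610 to 0.337 for Jarid2. The count of 21 genes (2 higher, 19 lower) became 180 (42 and 138) with the replicate block, 131 (8 and 123) with DESeq2, 97 (4 and 93) without a low-count filter and 32 (3 and 29) at a threshold of 0.1. Leaving out 1 library gave 0 to 27 genes (0 to 3 higher, 0 to 24 lower), with fewer samples in each such fit. The causes of the other changes were not tested. Other size factors, the stricter filter and library sizes without immunoglobulin genes gave 21, limma-voom 17 and the bias-adjusted test 28. The library sizes without immunoglobulin genes, the bias-adjusted test, the block combined with an estimated correlation or fry, and leaving out both libraries of a number were chosen after seeing the data. The 11 lists became 0 with an estimated correlation, with fry, and with either of these under the replicate block, 15 with the replicate block, 18 without both libraries of number 1 and 17 without both of number 3. Under the estimated correlation and fry, type I interferon-stimulated genes (median 0.49, with the block 0.45), interferon-gamma-inducible genes (0.40, with the block 0.40) and mature B and plasma cell genes (-0.85, with the block -0.86) kept their direction and did not pass, with adjusted p from 0.0597 to 0.532. Ighg2b, Igkc and Igha, named below in the ratios between isotypes, fell with the block (adjusted p 0.00583, 0.00477 and 0.0158 in edgeR). Without it they did not pass (0.0678, 0.228 and 0.353). The block changed no other call of a named gene or list than those given beside their values. The seed site difference stayed without a call, between 4.7e-05 and 0.016 when 1 library was left out. The pseudocount and low-value filter planned for normalized values were not run, since counts were tested. At these depths, 26% of simulated 1.5-fold changes were recovered, among the better counted genes that the simulation changed.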

Other observations

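The lists of immunoglobulin, plasma cell secretory and regulatory T cell genes, the ratios between isotypes, the heat shock comparison, the splits of the lists and of the blocked fit, the library sizes without immunoglobulin genes and the blocked test of the neighbourhood of the deleted locus were chosen after the results were seen. Plasma cell secretory genes (25 measured) had a median log2 fold change of -0.89, with 24 lower, 20 of them in all 3 pairs, and 12 that fell with the replicate block. Of 169 immunoglobulin genes, 164 were lower (median -2.61). Both lists passed at the preset correlation (camera adjusted p = 6.4e-26 and 1.2e-136) and not with an estimated one (adjusted p = 0.228 and 0.116). Derl3, of the degradation pathway of the endoplasmic reticulum (-1.78), and the transcription factor Irf4 (-1.14) fell with the block (adjusted p 0.00302 and 0.00217 in edgeR), whereas Hspa5 (0.08) and Sdf2l1 (-0.02) did not pass. Foxp3, the regulator of regulatory T cells, had 50 counts over the control libraries and 0 over the KO libraries, at least 13.8-fold lower against 3 counts over the group, with an adjusted p of 0.109 (0.0542 with the block). The regulatory T cell list (10 measured, 8 lower) had a median of -0.33, also with Foxp3 at that bound (camera adjusted p = 3.8e-05, 0.116 with an estimated correlation and 0.0122 with fry), and -0.55 without KO replicate 2 and -0.17 without KO replicate 3. Of its members 0 passed over all genes, and 2 fell with the block. Of the 42 genes that rose with the block, 18 belonged to the 68 tested members of both interferon lists. The heat shock genes Hspa1a, Hspa1b, Hsph1 and Dnajb1 had mean log2 ratios of 2.98, 2.48 and -0.12 in the pairs of numbers 1, 2 and 3, and none passed. Erdr1, whose reads can come from several copies, had 15 control and 138 KO counts and rose with the block (adjusted p 0.0302).

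Further genes that passed with the block, not without it, were also chosen after their values were seen. Of these the interferon-inducible Mx1 (0.84, adjusted p 0.0240 in edgeR), Ms4a4c (0.88, 0.0146) and the kinase Plk2 (0.80, 0.0381) rose. Reln, which encodes the secreted protein reelin (-2.09, 5.3e-04), Neb (-2.06, 0.0281), the calcium channel gene Cacna1h (-1.88, 0.0174), Oosp1 (-1.66, 0.0299) and Gpr55 (-1.57, 0.0342) fell.

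The 21 genes stood against 0 in each of the other 9 of 10 splits of the libraries, so 1 split gave as many, and 10 splits are too few for a share under 0.05. For the lists, 6 of the 10 splits gave at least the 11 of the real split and the highest other gave 18, which points to a structure of the samples that the preset correlation does not cover. The type I interferon list itself had p under 0.05 in 8 of the 9 other splits, with a smallest p of 3.3e-21 against 1.3e-25 in the real split, so its p at the preset correlation is no measure of the genotype difference alone. With the block, 2 of the 3 other splits that part all pairs had p under 0.05 for it, with a smallest of 5.6e-11 against 1.7e-39. Among the 4 splits that part all 3 pairs, 1 gave as many genes with the block as the real one, 180, and the highest other gave 0. For the lists with the block, 2 of these 4 splits gave at least the 15 of the real one, and the highest other gave 19. The 4 splits are again too few for such a share, and the other 3 mix both genotypes within each side.

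Fewer plasma cells among the sorted cells may account for the lower plasma cell genes, with the secretory genes at a median of -0.89, although lineage depletion would remove B cells that carry lineage markers, and the list was picked after immunoglobulin genes were seen to fall. Whether an equal loss of plasma cells of every isotype was the whole cause is not decided by Ighg1, Ighg2b and Ighg2c. They were taken because they were seen to fall, so a lower ratio to other plasma cell genes was built into the choice. The log2 ratio of their sum to Igj, Igkc and Mzb1 was 2.88 ± 0.18 (SD, n = 3) in the control and 0.67 ± 0.54 in the KO. The difference was -2.21 (exact permutation p = 0.1, the smallest possible), and -2.18 against Igj alone or -2.05 with Ighg3 in the sum. The ratio of Ighg3 alone differed by 0.87 (exact permutation p = 0.8), with 243 CPM in KO replicate 3 and 11.95 and 2.31 CPM in KO replicates 1 and 2, that of Igha by -0.42 (p = 0.5) and that of Ighm by 1.17 (p = 0.1). For the lists fixed beforehand, cells of another type in the gate cannot be told apart from a change within the cells, since no list had both a median beyond 0.5 in size and all abundant markers (a mean log2 CPM of at least 1, a limit chosen for this after the values were seen) moving together: mature B and plasma (median -0.85, or -1.52 and -0.40 without KO replicates 1 and 2; 6 of 7 abundant markers lower), neutrophil and monocyte (-0.52, 12 of 19), T and NK (-0.23 over 18 genes, or -0.03 without FLT3-ITD replicate 1 and -0.09 without KO replicate 2; 11 of 13) and mast cell, basophil and eosinophil (-0.13 over 9 genes, or -0.30 and -0.24 without FLT3-ITD replicates 1 and 3 and -0.02, -0.36 and -0.28 without KO replicates 1, 2 and 3; 7 of 7; within the limit of 0.2 set against this explanation, but with an SD of 0.65 between members). The deletion of miR-155 in the mice as the origin of either stays open and untested.

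Interferon-stimulated genes were higher in the KO. A single library as the whole source is argued against: 40 of 46 members were higher in all 3 pairs, with medians of 0.68, 0.40 and 0.30, and the list kept its call in 6 of 6 fits that left out 1 library (a weaker point, as other splits pass too), although KO replicate 1 adds to its size (median 0.23 without it). Immunoglobulin counts in the library sizes as the source are argued against for this list: its median was 0.487 without them and 0.489 with them. Leaving them out moved no list median by 0.05 or more. Stress during handling may contribute and stays open: the pair of number 3, whose heat shock genes were not higher, had a list median of 0.30, and there the immediate-early (0.22) and NF-kB (0.20) medians were positive, while the immediate-early median was -0.07 in the pair of number 2. The miR-155 deletion also stays open.

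Neighbouring genes of the deleted locus may carry differences of the strain in which the deletion was made. Without the block 0 of 63 tested genes within 10 Mb passed, where 0.0971 were due at the rate elsewhere, so Fisher's exact test (p = 1, two-sided) decides nothing, and an odds ratio of 0 was not read as evidence against this. With the block 3 of 63 passed (4.76%), against 1.33% elsewhere (Fisher's exact p = 0.0533, two-sided). They were Mrpl39 (-0.50), which lies 0.00233 Mb from the host transcript, Itsn1 (-0.56) and Urb1 (0.44). Immunoglobulin genes, 95 of which fell with the block, raise the rate elsewhere where they have coordinates. That rate was not computed without them. Mx1, which rose with the block, also lies on chromosome 16 (97447035 to 97462907), outside the 10 Mb. Ifnar1 (0.24), of the interferon receptor list, lies between Urb1 and Itsn1 and did not pass (adjusted p 0.348 in edgeR with the block). Whether this neighbourhood bears on the interferon-stimulated genes was not tested. The neighbourhood cannot be told apart from an effect of the deletion with so few calls.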
